A study of Mus musculus with 9 samples.

How the data were processed

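The samples were fibroblastic reticular cells (FRCs), the stromal cells that form the supporting network of lymph nodes, from female C57BL/6 mice. Per the labels and the series design text, each array held the FRCs of 2 brachial nodes pooled per animal, in 3 groups of 3 arrays: nodes draining a PBS injection site, nodes draining a tumour at day 4 and nodes draining a tumour at day 11. RNA was extracted with an RNeasy Plus Micro kit, amplified as whole transcriptome with the NuGEN Ovation PicoSL kit and labelled with biotin, per the labels' protocols. How the cells were isolated is not given in the sources used here.

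The deposited table of raw values held an intensity for each of 45281 Illumina bead probes per array, on a linear scale with no normalization between arrays, per the file headers and the values. Beside each intensity the deposited table held a detection p-value against negative control beads, per the file headers. The authors' processed values were also intensities on a linear scale, with a median of 113 in each of the 9 columns. Each column ranked its probes as the raw values of its sample did (rank correlation 1). These columns shared one distribution, whose mean of 222.8 differed from the mean of 210 over the raw values of these 9 arrays, so how the target of that normalization was made stays unknown. Per the deposited processing note, the authors used lumi, removed probes with no detection on any array of a comparison, applied a variance-stabilizing transformation and quantile normalization, and tested with limma.

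From the raw intensities, background correction and quantile normalization were done here with neqc of limma 3.58.1 in R 4.3.3, which takes the background from the detection p-values and adds an offset of 16 before log2. A probe was tested if its detection p was under 0.01 on at least 3 of the 9 arrays, which 16577 probes met. A symbol was taken from the platform annotation table given with the files, and 34885 probes had 1 symbol, 18 had several and 10378 were unnamed here. The symbols of 34807 probes were matched by gene identifier to the RefSeq gene table of assembly GRCm38.p6, which was used only for names. Each gene was counted by its probe with the highest mean, giving 8819 genes, of which 3323 had more than 1 tested probe.

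Group means were compared with lmFit and eBayes of limma over all 9 arrays, with 6 residual degrees of freedom and Benjamini-Hochberg adjustment over the tested probes at 0.05. Adjusted p-values in the text are from that fit unless another test is named. The 27 gene lists were written before the data were examined, as were the alternatives and the rule for named genes. Of these lists, 25 had at least 5 tested members and were tested with camera of limma at a preset correlation of 0.01 between genes, adjusted over the 75 tests. The adipocyte list, with 3 tested members, and the erythroid and platelet list, with 2, were not tested. Camera with an estimated correlation and fry were run beside it. Of the set tests, fry asks whether members move one way on balance, and its mixed form whether they change in either direction.

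The text names up to 8 of the largest rises and falls past the threshold whose groups did not overlap, leaving out symbols that are clone or locus identifiers and genes with another probe past the threshold in the opposite direction. Where none passed in a direction, the 3 genes with the lowest p in it were taken and are given as not passing. From each list, the 2 called members with the largest change were taken, or for a called list without such members the 2 with the lowest p. The 12 genes Pdpn, Pdgfra, Pdgfrb, Thy1, Ccl19, Ccl21a, Cxcl13, Cxcl12, Il7, Il6, Col1a1 and Acta2 were named whatever their result. Members that passed when adjusted over their list alone are also named, which was chosen after their values were seen. A gene detected on some array of each group keeps its log2 change, whose size is uncertain where a group mean lies near background. A gene not above background on any array of a group has only a bound there. Its fold is given as at least the brighter group's mean over the dimmer group's mean of, per array, the lowest signal among detected probes or the probe's own if higher.

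Alternatives were no background correction, scaling to the 75th percentile, the authors' processed values, other filters, other variance priors, array weights, the replicate number as a block, only the groups compared, the mean of a gene's probes, a stricter threshold and leaving out each array. The slide as a block was not run, since the column names and headers gave no slide. The pipeline was tested on simulated data with 200 of 8819 genes changed. For day 11 against PBS it recovered 0% of genes changed by 1 on the log2 scale, 73.5% of those changed by 2 and 97% of those changed by 3. For day 4 against PBS these shares were 0%, 71.5% and 99%, and for day 11 against day 4 they were 0%, 67% and 95.5%. A proliferation list raised by 0.5 at day 11 was called in 20 of 20 simulated data sets, and 2.6% of 1500 tests of unchanged lists had a p under 0.05. The simulated genes varied independently of each other. In the measured data the estimated correlation between members was 0.127 for the proliferation list and 0.585 for the myeloid list. The simulated shares therefore do not cover lists whose members are correlated. The number of arrays limits the precision: the median standard error of a log2 difference was 0.38.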

Results

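Gene expression was measured on 9 Illumina mouse bead arrays in FRCs of brachial lymph nodes, with 3 arrays for nodes draining a PBS site, 3 for tumour-draining nodes at day 4 and 3 for tumour-draining nodes at day 11. Between 9606 and 17627 of the 45281 probes were detected per array. The mean number was 14455 ± 2597 (SD, n = 3) in PBS, 16129 ± 1310 at day 4 and 11850 ± 2618 at day 11. The median raw intensity was 131 ± 18.2 at day 11, against 96.8 ± 5.78 in PBS and 97.8 ± 14.7 at day 4. Day 11 arrays correlated with each other across probes at a mean of 0.920, day 4 arrays at 0.853 and PBS arrays at 0.804. PBS replicate 1 had the lowest mean correlation with its own group, 0.783. Probes are not independent replicates, so these correlations describe the arrays. The PBS arrays serve as controls in both tumour comparisons.

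The first comparison asked how FRCs differed early, at day 4 of tumour drainage, from FRCs of nodes draining PBS. The proliferation genes, which drive DNA replication and mitosis, rose as a list at day 4, with a median log2 change of 0.41 over 33 members (camera, adjusted p = 0.0032; adjusted p = 0.755 with an estimated correlation). Of these members 26 were higher and 7 lower, and none passed on its own. Birc5, a mitotic survivin, had a log2 change of 1.46 ± 0.47 (SE, n = 3 per group; limma adjusted p = 0.472), and its other probes gave 0.18 and 0.72. Its PBS mean of 5.11 lay near background, so the size of this change is uncertain. Rrm2, a subunit of ribonucleotide reductase, had 0.87 ± 0.29 (limma adjusted p = 0.490). The list call was lost without PBS replicate 2 or day 4 replicate 2 (highest camera adjusted p = 0.172), and the median was 0.23 with those steps of the deposited processing note available here.

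The oxidative phosphorylation genes, which encode the mitochondrial respiratory chain, also rose as a list at day 4, by a median of 0.16 over 62 members (camera, adjusted p = 0.0396; adjusted p = 0.755 with an estimated correlation). Of these, 45 were higher and none passed on its own. The call was lost without any one of PBS replicate 1, PBS replicate 3, day 4 replicate 2 and day 11 replicate 3 (highest camera adjusted p = 0.464). The median was 0.07 without day 4 replicate 2, 0.26 without day 4 replicate 1, 0.24 without day 4 replicate 3 and 0.24 without PBS replicate 2. The complex I subunit Ndufs7 had a log2 change of 1.004 ± 0.34 (limma adjusted p = 0.506). Its fellow subunit Ndufs1 was not above background in PBS and was at least 1.62-fold higher at day 4 (limma adjusted p = 0.375). The ribosomal protein list, fixed as a check on RNA quality and amplification, had a median of 0.06 with 39 of 54 members higher. It did not pass (camera, adjusted p = 0.829). Myeloid cell markers fell as a list, by a median of -0.28 over 15 members (camera, adjusted p = 0.00472; adjusted p = 0.755 with an estimated correlation). Of these, 2 were higher and 13 lower. This call was lost without PBS replicate 2 or day 4 replicate 3 (highest camera adjusted p = 0.271). The median was -0.12 without PBS replicate 2, -0.66 without PBS replicate 1 and -0.69 without day 4 replicate 2. The T cell and B cell marker lists had medians of -0.31 and -0.13 and did not pass (camera, adjusted p = 0.160 and 0.586). Fcer1g, the Fc receptor gamma chain, was not above background at day 4 and was at least 1.68-fold higher in PBS (limma adjusted p = 0.372). Lyz2, a macrophage lysozyme, had a log2 change of -0.77 ± 0.34 (limma adjusted p = 0.619).

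No gene passed the threshold at day 4 in limma, with 0 higher and 0 lower, while 416 genes were higher and 289 lower at an unadjusted p under 0.05, 7.99% of the 8819 tested against 5% by chance. Another split of the same 6 arrays gave 755 such genes. The groups did not overlap in 10.5% of genes, against 10% by chance. The genes with the lowest p among those higher at day 4 were Rhobtb1 (log2 change 2.42 ± 0.35), Nfasc, a neuronal adhesion molecule, and Insl3, a peptide hormone. All 3 had an adjusted p of 0.285 in limma, and a dimmer second probe of Rhobtb1 gave 0.07. Rhobtb1 had a PBS mean of 5.67, near background, so the size of its change is uncertain. Nfasc and Insl3 were not above background in PBS and were at least 1.80-fold and 1.78-fold higher at day 4. The lowest p among lower genes belonged to the ribosomal protein gene Rpl6 (-1.85 ± 0.33), Gal3st2b and Dnmt3b, a DNA methyltransferase, each with a limma adjusted p of 0.285. Rpl6 had a day 4 mean of 5.12, near background, so the size of its change is uncertain. Most of the ribosomal protein list was higher at day 4. Gal3st2b and Dnmt3b were not above background at day 4 and were at least 2.92-fold and 2.93-fold higher in PBS.

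When adjusted over the list alone, 1 or 2 members passed in 5 lists at day 4. Among inflammatory cytokines, the interleukin gene Il1b fell by 1.75 (limma, adjusted p = 0.0475 over the list alone). Ccl4, a chemokine, fell as well and was not above background at day 4, at least 2.78-fold below PBS (limma, adjusted p = 0.00765 over the list alone). The inflammatory list as a whole had a median of 0.09 and a mean of -0.18, and its test pointed down without passing (camera, adjusted p = 0.777). Cyp51, an enzyme of cholesterol synthesis, rose and was not above background in PBS, at least 1.90-fold below day 4 (limma, adjusted p = 0.0067 over the list alone). Cd3e, a subunit of the T cell receptor complex, fell by 1.61 (limma, adjusted p = 0.00445 over the list alone), and Rpl6 and Fcer1g also fell over their own lists. Cd3e had a day 4 mean of 5.78, near background, so the size of its fall is uncertain. The FRC identity list had a median change of 0.04 over 28 members and the T zone chemokine list 0.10 over 21 members, and neither passed (camera, adjusted p = 0.806 and 0.864). The matrix, TGF-beta, immediate early and pericyte lists had medians and means above 0 with tests against the other genes that pointed down, the lymphatic endothelial list had a median below 0 and a mean above 0, and none of these passed. Among the preset genes, the FRC surface marker Pdpn had a log2 change of 0.29 ± 0.26, the T cell zone chemokine Ccl19 0.33 ± 0.28 and the cytokine Il6 0.31 ± 0.28. The growth factor receptors Pdgfra and Pdgfrb had -0.08 ± 0.27 and 0.36 ± 0.35, Thy1 -0.24 ± 0.32, Ccl21a 0.11 ± 0.28, Cxcl13 0.06 ± 0.28, Cxcl12 0.12 ± 0.24, the T cell survival factor Il7 0.21 ± 0.31 with another probe at -0.73, Col1a1 0.06 ± 0.26 and the smooth muscle actin Acta2 0.45 ± 0.31. None of the 12 passed when adjusted over these genes alone. Ccl21a shares nearly all of its sequence with other Ccl21 copies, so its level is uncertain.

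The second comparison asked how FRCs differed from PBS later, at day 11. Ighg1, an immunoglobulin heavy chain constant region gene, was the 1 gene that passed: it was not above background on any PBS array and was at least 10.3-fold higher at day 11 (limma adjusted p = 0.0166), with a mean log2 level of 9.40 ± 0.92 (SD, n = 3) against 4.97 ± 0.28. The proliferation genes rose as a list, by a median of 0.80 over 33 members, of which 30 were higher (camera, adjusted p = 4.22e-09; adjusted p = 0.755 with an estimated correlation). The median was 0.52 with the authors' values, 0.45 with no background correction and 0.40 with the steps of the deposited note. Adjusted over the list alone, 9 members rose and 0 fell, while none passed over all probes. Birc5 rose by 2.92 ± 0.47 (limma, adjusted p = 0.00299 over the list alone and adjusted p = 0.194 over all probes), and its other probes gave 0.90 and 1.53. The mitotic genes Cdca8 (2.32 ± 0.60), Plk1 (2.03 ± 0.53) and Aurka (1.33 ± 0.44), Rrm2 (1.29 ± 0.29), the replication factor Mcm5 (1.70 ± 0.56) and the chromatin protein gene Hmgb2 (1.01 ± 0.32) were among the 9. The PBS means of Birc5 and Aurka, 5.11 and 5.74, lay near background, so the sizes of their changes are uncertain. Cdca3, a regulator of mitotic entry, and Tyms, which makes thymidylate, were not above background in PBS and were at least 2.84-fold and 1.58-fold higher at day 11.

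**Figure D1:**
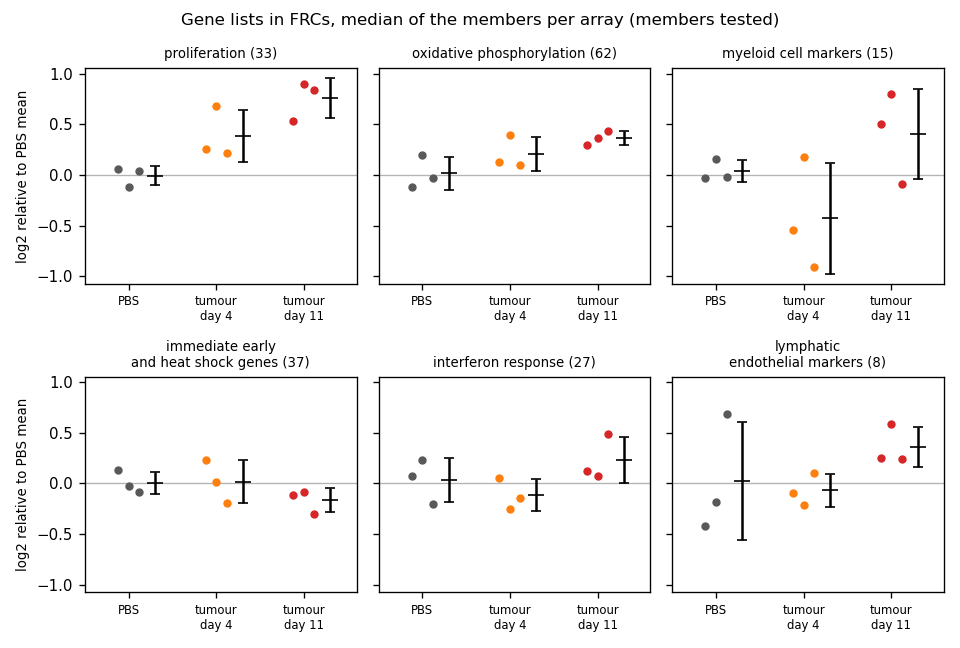
Median log2 level of the members of 6 gene lists on each array, relative to the mean of the 3 PBS arrays, for PBS, tumour day 4 and tumour day 11 (points, arrays; horizontal marks and bars, mean and SD of 3 arrays; the number of tested members stands beside each name). The proliferation and oxidative phosphorylation points of all 3 day 11 arrays lie above those of all 3 PBS arrays, and the myeloid points spread widely at day 4 and day 11.

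The oxidative phosphorylation genes rose as a list at day 11, by a median of 0.36 over 62 members, of which 56 were higher (camera, adjusted p = 6.6e-05; adjusted p = 0.755 with an estimated correlation). No member passed on its own, and the lowest p belonged to Ndufa9 (0.90 ± 0.29) and Atp5j (0.77 ± 0.29), subunits of complex I and of ATP synthase. One of the other Atp5j probes gave -0.68. The ribosomal protein list, the check on RNA quality and amplification, moved the same way without passing. Its median was 0.20 with 43 of 54 members higher (camera, adjusted p = 0.160). Whether RNA quality or amplification differed between the groups was not tested. Immediate early and heat shock genes were listed as genes known to rise during tissue digestion and sorting. A difference in handling cannot be told apart here from a response in the node. They fell as a list by a median of -0.11 over 37 members (camera, adjusted p = 0.0112; adjusted p = 0.755 with an estimated correlation). Of these, 7 were higher, and the lowest p belonged to Jund (-1.08 ± 0.39) and Btg2 (-0.65 ± 0.26), neither of which passed. The call was lost without PBS replicate 1 or day 11 replicate 3 (highest camera adjusted p = 0.206), and the median was -0.21 with 75th percentile scaling, -0.18 without PBS replicate 3 and -0.17 without day 11 replicate 2. The myeloid list had a median of 0.31 (camera, adjusted p = 0.177), the B cell list -0.14 (adjusted p = 0.829) and the T cell list -0.12 (adjusted p = 0.586), so none of these passed at day 11. The plasma cell list (0.64; adjusted p = 0.829), the blood endothelial list (0.52; adjusted p = 0.186) and the pericyte and smooth muscle list (-0.30; adjusted p = 0.182) did not pass either. The lymphatic endothelial list had a median of 0.34 and did not pass (camera, adjusted p = 0.105). It was called with 75th percentile scaling, the authors' values and no background correction (camera, adjusted p = 0.0471, 0.0397 and 0.0319).

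Of the FRC identity genes, 17 of 28 were higher at day 11, and the list did not pass (median 0.20; camera, adjusted p = 0.160). Adjusted over the list alone, Thy1, a surface glycoprotein of fibroblasts and T cells, rose by 1.53 ± 0.32 (limma, adjusted p = 0.0186) and Ly6c1 rose by 1.40 ± 0.32 (adjusted p = 0.0188). Thy1 also passed over the 12 preset genes alone (limma, adjusted p = 0.00798), and Pdpn, at 0.74 ± 0.26, did not (adjusted p = 0.102). The T zone chemokine and survival factor list had a median of -0.14 with 9 of 21 higher (camera, adjusted p = 0.654), and its mean was 0.02. Its member Cxcl14, a chemokine, rose when adjusted over the list alone (limma, adjusted p = 0.0017) and was not above background in PBS, at least 2.33-fold below day 11. Ccl19 had a log2 change of -0.18 ± 0.28, Ccl21a -0.31 ± 0.28, Cxcl12 -0.14 ± 0.24, Cxcl13 0.11 ± 0.28 and Il7 -0.43 ± 0.31, with all 3 Il7 probes lower. Il6 had 0.21 ± 0.28, Pdgfra -0.19 ± 0.27, Acta2 0.15 ± 0.31 and Col1a1 -0.00215 ± 0.26, and Pdgfrb was not above background at day 11.

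Further members rose at day 11 when adjusted over the list alone. The interferon-induced genes Isg15 and Bst2 rose by 1.54 ± 0.32 and 1.53 ± 0.39 while their list did not pass (median 0.29; camera, adjusted p = 0.127). Without day 11 replicate 3 the list median was -0.0093 (camera, adjusted p = 0.717). The list was called without day 11 replicate 1 or day 11 replicate 2 (camera, adjusted p = 0.0445 and 0.0276). Over their lists alone, the hypoxia-responsive genes Adm and Pfkfb3 rose by 1.34 ± 0.30 and 1.32 ± 0.32, and the asparagine synthetase gene Asns rose by 2.07 ± 0.36. The PBS means of Adm, Pfkfb3 and Asns were 5.95, 5.94 and 5.54, near background, so the sizes of these rises are uncertain. Among the lymphatic endothelial markers, Ptx3, a secreted pentraxin that fibroblasts also make, rose by 2.98 ± 0.56. The actin crosslinker Actn4 fell by 1.60. Among lower genes over all probes, the lowest p belonged to Cyp2f2, a cytochrome P450 (-2.15 ± 0.32), Gal3st2b and Rpl6, each with a limma adjusted p of 0.194. Gal3st2b and Rpl6 were not above background at day 11 and were at least 1.79-fold and 1.42-fold higher in PBS. The only tested Rpl6 probe was dim, with a mean of 5.76 over all arrays, while 43 of 54 ribosomal protein genes were higher at day 11. Its fall is therefore not a fall of the ribosomal list.

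In limma 1 gene was higher and 0 lower, against 545 higher and 359 lower at an unadjusted p under 0.05, 10.3% of genes against 5% by chance. The groups did not overlap in 18.2% of genes, against 10% by chance. The Ighg1 call was lost when any 1 of the arrays other than day 11 replicate 3 was left out (limma adjusted p from 0.0576 to 0.174), and its adjusted p ranged from 0.00133 to 0.201 over 22 alternatives, 9 of which kept the call. With a variance prior that follows intensity, 10 genes were higher and 1 lower.

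**Figure D2:**
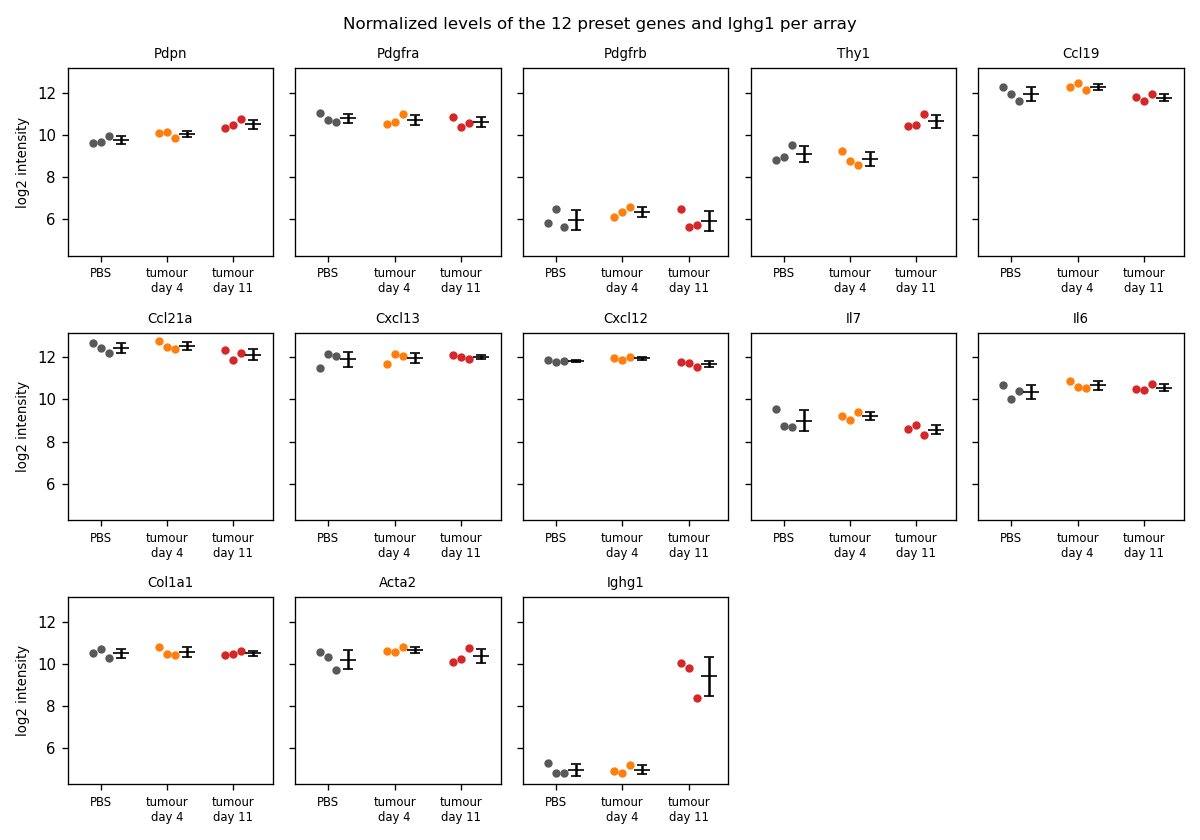
Normalized log2 intensity of the 12 preset genes and Ighg1 on each array, for PBS, tumour day 4 and tumour day 11 (points, arrays; horizontal marks and bars, mean and SD of 3 arrays). Ighg1 lies between 8.35 and 10.04 on the day 11 arrays and at or below 5.29 on the others, and Thy1 has means of 9.12 in PBS, 8.88 at day 4 and 10.65 at day 11.

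The third comparison set day 11 against day 4, which equals the difference between the changes from the shared PBS group. The labels give that group no day, so a tumour effect and time itself cannot be told apart. Ighg1 was not above background at day 4 and was at least 12.4-fold higher at day 11 (limma adjusted p = 0.0167), the 1 gene that passed. Myeloid cell markers rose as a list, by a median of 0.87, with all 15 members higher (camera, adjusted p = 7.26e-07; adjusted p = 0.755 with an estimated correlation). Tyrobp, a signalling adaptor of myeloid cells, had a log2 change of 1.40 ± 0.39 and Lyz2 1.06 ± 0.34, and neither passed on its own. The median was 0.57 without day 11 replicate 2. Array medians of the list overlapped between the groups, from -0.91 to 0.17 at day 4 and from -0.08 to 0.79 at day 11 relative to PBS. The T cell and B cell lists had medians of 0.33 and 0.11 and did not pass (camera, adjusted p = 0.469 and 0.829). Interferon response genes rose as a list by a median of 0.29 over 27 members, of which 22 were higher (camera, adjusted p = 0.000365; adjusted p = 0.755 with an estimated correlation). The median was 0.18 with no background correction and 0.14 with the steps of the deposited note. Without day 11 replicate 3 it was 0.05 and the call was lost (camera adjusted p = 0.0896). Adjusted over the list alone, Isg15 rose by 1.81 ± 0.32, Ifi204 by 2.05 ± 0.42 and Bst2 by 1.42 ± 0.39.

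Proliferation genes rose as a list from day 4 to day 11, by a median of 0.57 with 26 of 33 higher (camera, adjusted p = 0.000346; adjusted p = 0.755 with an estimated correlation). The median was 0.35 with the authors' values, 0.34 with no background correction and 0.29 with the steps of the deposited note. The mitotic kinase gene Aurka had a log2 change of 1.56 ± 0.44 and Rrm1 1.001 ± 0.30, and neither passed. Aurka had a day 4 mean of 5.51, near background, so the size of its change is uncertain. Other Rrm1 probes gave 0.47 and 0.23. The ribosomal protein list had a median of 0.11 with 45 of 54 members higher and did not pass (camera, adjusted p = 0.172). The oxidative phosphorylation list had 0.16 with 46 of 62 higher and did not pass (camera, adjusted p = 0.0812). It was called with the authors' values, no background correction and the steps of the deposited note (camera, adjusted p = 0.0397, 0.0317 and 0.0301). With 75th percentile scaling it was not (camera, adjusted p = 0.256). The lymphatic endothelial list rose by a median of 0.57 with 7 of 8 members higher (camera, adjusted p = 0.0112; adjusted p = 0.755 with an estimated correlation). Its members that rose when adjusted over the list alone were Thy1 (1.77 ± 0.32) and Ptx3 (1.87 ± 0.56), both of which fibroblasts also express. Of the 17 genes fixed for this list, tested or not, 6 stand on other lists. The list median was 0.30 with the authors' values, 0.26 with no background correction and 0.19 with the steps of the deposited note, and the call was lost without day 4 replicate 2 (camera adjusted p = 0.0800). Immediate early and heat shock genes fell as a list by a median of -0.20 with 9 of 37 higher (camera, adjusted p = 0.0124; adjusted p = 0.755 with an estimated correlation). The median was -0.09 without day 11 replicate 3 and -0.34 without day 4 replicate 3, and the call was lost without day 4 replicate 1, day 4 replicate 2 or day 11 replicate 3 (highest camera adjusted p = 0.188). Ier5 had a log2 change of -0.94 ± 0.26 and Jund -0.76 ± 0.39.

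Adjusted over the list alone, Thy1 and Ly6c1 (1.23 ± 0.32) of the FRC identity list, Il1b (2.10 ± 0.51), Asns (1.64 ± 0.36) and Cd3e (1.29 ± 0.33) also rose from day 4 to day 11. The day 4 means of Asns and Cd3e, 5.97 and 5.78, lay near background, so the sizes of their rises are uncertain. Cxcl14 rose over its list alone and was not above background at day 4, at least 2.79-fold below day 11. The plasma cell and melanocyte lineage lists had medians below 0 and means above 0, the lipid list had a median above 0 with a test that pointed down, the complement list had a median below 0 and a mean above 0, and none of these passed. The lowest p among lower genes belonged to Nfasc, Draxin (-1.52 ± 0.30) and Rhobtb1 (-1.72 ± 0.35), each with a limma adjusted p of 0.487. Nfasc was not above background at day 11 and was at least 1.32-fold higher at day 4. Among preset genes, Ccl19 had a log2 change of -0.51 ± 0.28, Ccl21a -0.42 ± 0.28, Il7 -0.65 ± 0.31, Cxcl12 -0.25 ± 0.24 and Pdpn 0.46 ± 0.26. Cxcl13 had 0.04 ± 0.28, Pdgfra -0.11 ± 0.27, Il6 -0.10 ± 0.28, Col1a1 -0.06 ± 0.26 and Acta2 -0.29 ± 0.31. Pdgfrb was not above background at day 11. Thy1 passed over the 12 genes alone (limma, adjusted p = 0.00265) and the others did not.

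In limma 1 gene was higher and 0 lower, with 274 higher and 295 lower at an unadjusted p under 0.05, 6.45% of genes against 5% by chance. The groups did not overlap in 15.5% of genes, against 10% by chance. The Ighg1 call was lost without PBS replicate 2, any 1 of the day 4 arrays, day 11 replicate 1 or day 11 replicate 2 (limma adjusted p from 0.0544 to 0.159).

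No gene was called in both tumour comparisons against PBS, since 0 were called at day 4. At an unadjusted p under 0.01, 180 genes were counted at day 4 and 255 at day 11, and 57 were in both with the same direction. In 100 simulations of unchanged groups against the same PBS arrays, means of 96.6 and 97.7 genes were counted and 17.2 were in both. Independent lists would share 2.88 genes at the measured sizes and 0.537 at the simulated sizes. The log2 changes at the different times correlated across genes at 0.602, against 0.50 in the simulation, and their covariance was 0.178 against 0.109. In the simulation the shared PBS arrays alone thus gave 17.2 shared genes against 0.537 and a correlation of 0.50. The measured 57 and 0.602 were larger, but so were the numbers of genes counted, and the PBS arrays were too few to split. A common response at day 4 and day 11 is therefore not shown.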

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

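The tests of the myeloid source, the FRC share, the dividing leukocytes, PBS replicate 1 and Ighg1 were chosen only after the result was seen. The results here were picked because the changes from PBS at day 4 and day 11 differed by the test of day 11 against day 4. With PBS arrays of no stated day, that test does not separate tumour drainage from time.

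The proliferation list was higher at day 11 than at day 4 by a median log2 change of 0.57, and by 0.80 than in PBS (for both, adjusted p = 0.755 with an estimated correlation). Background correction or normalization alone is argued against, since at the fixed small correlation the list kept its call with no background correction, 75th percentile scaling and the authors' values, with a lowest median of 0.45 against PBS and 0.34 against day 4, both with no background correction. Leaving out PBS replicate 1 gave a median of 0.92, which was no real test of that array. Its list median relative to the PBS mean was 0.06, the highest of the PBS arrays (-0.12 and 0.04 for replicates 2 and 3). Leaving it out was thus bound to keep the rise. The median against PBS was 0.73 without PBS replicate 2 and 0.68 without day 11 replicate 2. At the fixed small correlation the call was kept without each of the 9 arrays. Dividing leukocytes in the samples stay open: the B cell, T cell and myeloid lists had medians up to 0.31 and did not pass against PBS, and the myeloid list rose from day 4 to day 11 as well, which decides nothing. The biological difference in the design, tumour drainage, was not separable from such cells.

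The myeloid cell marker list was higher at day 11 than at day 4 by a median log2 change of 0.87 (0.57 without day 11 replicate 2), with array medians that overlapped between the groups and an estimated correlation of 0.585 between members (adjusted p = 0.755 with an estimated correlation). One day 4 array alone is argued against, since at the fixed small correlation the list kept its call without each of them (highest adjusted p = 0.00121). Myeloid cells or their RNA in the samples may be a source. That all 15 members were higher restates the rise of the list and decides nothing about its source. Among them were the abundant Laptm5 (0.64 ± 0.31), Lyz1 (0.99 ± 0.33) and Lyz2 (1.06 ± 0.34), and 1 gene of the list stands on another list. A lower share of FRCs, raising all other cell types alike, stays open, since the test against it rests on pericyte genes. If FRCs express these, a lower share would lower them, and Acta2 of that list had a mean log2 level of 10.6 at day 4. In that test, 7 pericyte genes on no other list and above background had a median of -0.31 (SD 0.346 between members). The value was 0.86 (SD 0.375) for 10 such myeloid genes. With all members, the B cell (0.11), plasma cell (-0.27) and blood endothelial (0.30) lists also lay below the myeloid list by more than the spread. The T cell (0.33, SD 0.762) and lymphatic endothelial (0.57, SD 0.754) lists did not. Of genes on no other list and above background, 4 B cell genes (-0.17, SD 0.582) and 3 blood endothelial genes (0.20, SD 0.645) lay below by more than the spread. The 3 plasma cell genes (0.91, SD 1.12), 2 T cell genes (0.22, SD 0.895) and 2 lymphatic endothelial genes (0.94, SD 1.32) did not. Each of these sets held fewer than the 5 genes asked of a list. The FRC identity list had a median of 0.16 and the T zone chemokine list -0.15, and neither passed (camera, adjusted p = 0.363 and 0.441). A change of these genes within FRCs at the different times was not tested, and the labels name no gate.

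Ighg1 was not above background at day 4 and was at least 12.4-fold higher at day 11 (limma adjusted p = 0.0167), and the difference of 4.43 between log2 means rests on an undetected probe and measures no fold. The call was lost against PBS without any 1 array other than day 11 replicate 3 (limma adjusted p from 0.0576 to 0.174), and against day 4 without PBS replicate 2, any 1 of the day 4 arrays, day 11 replicate 1 or day 11 replicate 2 (0.0544 to 0.159). Background or normalization alone is argued against, since its probe was detected on all 3 day 11 arrays and the call against PBS held under the 3 other normalizations (highest limma adjusted p = 0.019, within a range of 0.00133 to 0.201 over 22 alternatives, of which 9 kept the call), while it was lost after the deposited processing note (0.0755), which also takes only the 2 groups compared, a choice that alone lost it (0.201). Plasma cells or their RNA in the samples cannot be told apart from other sources: the plasma cell list had a median of -0.27 against day 4, with 2 of 6 members higher, and 0.64 against PBS, with Fkbp11 at 1.74 ± 0.55, Eaf2 at -1.25 ± 0.30 and Jchain at -0.43 ± 0.56. Fkbp11 had a PBS mean of 5.73, near background. No biological explanation was tested.

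The interferon response list was higher at day 11 than at day 4 by a median log2 change of 0.29 (adjusted p = 0.755 with an estimated correlation), by 0.18 with no background correction, by 0.14 after the processing note, and by 0.05 without day 11 replicate 3 (camera adjusted p = 0.0896). The immediate early and heat shock list was lower by a median of -0.20 (adjusted p = 0.755 with an estimated correlation), which was -0.09 without day 11 replicate 3 and -0.34 without day 4 replicate 3, and the call was lost without day 4 replicate 1, day 4 replicate 2 or day 11 replicate 3 (camera adjusted p = 0.188, 0.0665 and 0.0915). These genes rise during tissue digestion and sorting, and a difference in handling was not tested. The lymphatic endothelial list was higher by a median of 0.57 (adjusted p = 0.755 with an estimated correlation), by 0.30 with the authors' values, 0.26 with no background correction and 0.19 after the processing note, and lost its call without day 4 replicate 2 (camera adjusted p = 0.0800).

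The 6 arrays of a comparison make 10 splits, too few for a share under 0.05. For genes, the real split against the highest of the others gave 0 and 0 at day 4 against PBS (10 of 10 splits gave as many), 1 and 0 at day 11 against PBS (1 of 10) and 1 and 0 at day 11 against day 4 (1 of 10). For gene lists these were 3 and 3 (3 of 10), 3 and 3 (2 of 10) and 5 and 5 (2 of 10). At an unadjusted p under 0.05, the real split and the highest of the others gave 705 and 755 genes at day 4 against PBS, 904 and 442 at day 11 against PBS, and 569 and 341 at day 11 against day 4.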

How the results depend on the processing

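The alternative after the deposited processing note and the lists with no background correction were chosen after seeing the data. The replicate block gave 0 genes higher at day 11 against PBS and 0 against day 4, and changed no count of lists. Deviations of same-numbered arrays correlated between -0.0461 and 0.0628, and 2 of 9 arrays correlated best with their own number in both other groups, so the numbers were not taken as pairing. For day 11 against PBS, 3 genes were higher and 1 lower with no background correction, 10 higher and 1 lower with the trended variance prior, and 0 higher with no detection filter, with only the 2 groups compared, at adjusted p under 0.01 and after the processing note. Leaving out an array gave 0 to 1 higher. For day 11 against day 4, 0 were higher with no filter, with only the 2 groups and at adjusted p under 0.01, 2 with the trended prior, 4 after the note, and 0 to 1 without one array. Testing all probes, using fewer arrays and a stricter threshold make calls rarer by construction, and for the other changes the cause was not tested. Lists called higher and lower fell to 0 in each comparison with an estimated correlation and with directional fry, while mixed fry, which gives no direction, called 2, 10 and 5 lists. Without one array, lists higher ranged from 0 to 2 and lower from 0 to 1 at day 4 against PBS, from 2 to 4 and 0 to 1 at day 11 against PBS, and lower from 0 to 2 at day 11 against day 4. The processing note gave 4 lists higher at day 11 against PBS. At an unadjusted p under 0.01, 57 genes were shared by day 4 and day 11. Of the values for single genes and lists over these alternatives, 1771 stayed on their side of the threshold, 34 of them uncalled with a changed sign, while 60 lost a call and 19 gained one. The slide as a block was not run. Signal near background limits the dim probes, whose median residual SD was 0.6, against 0.33 in the brightest tercile.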

Other observations

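The list of adventitial genes was tested only after other genes had been seen. It was written before its own members were looked at singly, although 6 of them stand on lists that had been tested earlier. The histone genes, Cd34, Cd248, Pi16, Inmt and the members named singly were chosen after their values were seen.

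Histone genes that are transcribed during DNA replication were higher at day 11 than in PBS as a family taken by symbol. Of 45 tested, 42 were higher and 3 lower, with a median log2 change of 1.08 (camera p = 6.61e-22; p = 0.00677 with an estimated correlation), and 28 rose when adjusted over the family alone, while 0 passed over all probes in limma. Over 12 other settings, which were 3 other normalizations and each array left out, the median lay between 0.77 and 1.10 there, between 0.28 and 0.52 at day 4 against PBS and between 0.48 and 0.66 from day 4 to day 11. At day 4 against PBS the median was 0.43 with 34 higher (camera p = 2.09e-05; p = 0.125 with an estimated correlation, and p = 0.0400 with that and without day 4 replicate 3), and from day 4 to day 11 it was 0.57 with 42 higher (camera p = 3.92e-15; p = 0.0164 with an estimated correlation, and p = 0.0514 with that and 75th percentile scaling). With the variance prior that follows intensity, H2bc14 (1.66 ± 0.27), H2bc12 (1.40 ± 0.29), H3c6 (1.52 ± 0.33), H2bc11, H2bc6 and H3c10 passed at day 11 against PBS. Their being seen there led to the family, so its p-values are not independent evidence. Many of these genes are near-identical copies, so single members are uncertain and members are not independent.

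A hypothesis is that day 11 FRCs held a larger share of CD34-positive adventitial stromal cells. Thy1 and Ly6c1 rose over their list alone, and Cd34 (1.02 ± 0.39), Cd248 (0.60 ± 0.31) and Pi16 (1.08 ± 0.62), markers of such cells, had positive log2 changes against PBS that did not pass, while Inmt had -1.015 ± 0.30. Ly6c1 and Cd34 also stand on the blood endothelial list, whose median was 0.52 against PBS, and Thy1 on the lymphatic endothelial list. These genes therefore do not tell adventitial from endothelial cells. A list of 24 other adventitial genes, 20 of them tested and 6 of them also on the lists fixed earlier, had a median of 0.70 against PBS with 16 higher (camera p = 0.00952; p = 0.262 with an estimated correlation). Against day 4 the median was 0.53 with 18 higher (camera p = 3.62e-05; p = 0.096 with an estimated correlation). Mfap5 had 1.64 ± 0.53 and Anxa3 0.79 ± 0.35 against PBS, while Scara5 had -0.84 ± 0.24 and Limch1 -1.07 ± 0.36. The camera p against PBS was 0.0841 without PBS replicate 1 and 0.139 without day 11 replicate 3. The medians against PBS without these arrays were 0.31 and 0.46. Against day 4 it was 0.34 without day 4 replicate 2, 0.34 without day 11 replicate 3 and 0.82 without day 4 replicate 1. These values are in line with the hypothesis only where members are taken as nearly independent, and a change of these genes within FRCs was not tested.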
